A study of Homo sapiens with 18 samples.

How the data were processed

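Circular RNAs were measured by RNA sequencing in MCF7 cells, an established human breast cancer line, and in exosomes, the small vesicles that the cells released. The 18 libraries formed 6 groups of 3, with the labels Con, kd and Re in cells and the same 3 labels in exosomes. The series names LSD1 as its subject, the histone demethylase encoded by KDM1A. The labels do not spell out kd or Re. Cell RNA was isolated with a miRNeasy Micro kit and made into libraries with a VAHTS Universal V6 kit. Exosome RNA was isolated with an exoRNeasy Maxi kit and made into libraries with a SMARTer Stranded Total RNA-Seq kit, so compartment and kit cannot be told apart in any comparison of exosomes with cells. The labels do not say whether the 3 libraries of a group came from separate cultures, so every p-value measures only the spread between libraries.

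The deposited values were counts of back-splice junction reads per circular RNA, the reads that cross the join between a downstream and an upstream splice site. The authors gave 1 list of circular RNAs per compartment, with no further normalization. The submitters' notes name GRCh38, HISAT2 and StringTie without saying what each was used for, and the program that called the circles is not given. The smallest count above 0 was 2 and no count of 1 occurred, so a 0 may stand for 1 read that was not listed. The depth in mapped reads is not in the files. Library totals below are sums of listed junction reads and depend on how many circles were listed.

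Each circle was placed on the GENCODE release 29 annotation of GRCh38 by its chromosome, strand, start and end. Positions are counted from 1. A circle was assigned to a host gene when both ends met annotated exon ends of that gene on its strand. It was assigned to both genes when its ends met exon ends of different genes. A host was also given to circles with 1 end at an exon end (251 in cells, 162 in exosomes). The same held for circles inside a gene with no end at an exon end (39 and 66). Both kinds enter the gene lists. Exons were numbered along the transcript that fit both ends. The files carry no circBase identifiers, so none of the known circular RNAs listed beforehand was matched, and no circle is called by such a name.

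Counts were fitted with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM (trimmed mean of M-values) factors and group as the only term. All 9 libraries of a compartment entered each fit within it, and all 18 entered the fits across compartments. A circle was tested when at least 3 of the 9 libraries of a compartment held at least 2 reads, which left 497 circles in cells and 113 in exosomes. In the fits across compartments, passing in either compartment was enough, which left 545. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the circles tested, with a threshold of 0.05. Levels are given as reads per 1000 effective junction reads, the library total multiplied by its TMM factor. Beside a group in which every library was at 0, the fold is a nominal lower bound, given as at least and computed against 3 reads over the group. A fitted log2 fold change beside such a group depends on the prior count and is no bound. The bounds cover counting error only, since amplified reads are not independent molecules. Library totals and numbers of circles were compared by exact permutation tests, two-sided, whose smallest possible p is 0.1 for 3 against 3.

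The scaling set the center of the comparisons. With library totals in place of TMM, the log2 fold changes of single circles moved by a median of 0.47 for kd against Con in cells and 0.55 in exosomes. They moved by a median of -0.56 and -1.01 for Re against kd, -0.08 and -0.45 for Re against Con, and 0.56 for exosomes against cells. With relative log expression (RLE) factors the median moves were 0.28, 0.58, -0.31, -0.70, -0.03, -0.19 and 0 in the same order. For kd against Con, the median log2 fold change itself went from -0.60 with TMM to -0.04 by library totals in cells. In exosomes it went from -0.93 to -0.30. Fold changes are therefore relative to the TMM center, and a call that rests on it is named.

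For each of 15 gene lists fixed before the data were examined, circles were assigned by host gene. Lists with at least 5 tested circles entered camera and fry of limma 3.58.1, camera with a preset correlation of 0.01 and again with an estimated one. The lists covered the LSD1 and CoREST complex, other chromatin modifiers, estrogen and luminal genes, the amplified 17q and 20q regions of MCF7, circular RNA biogenesis proteins, the miRNA pathway, vesicle biogenesis, adhesion and epithelial-mesenchymal transition, cell cycle, and ubiquitin ligases. Markers of fibroblasts, blood and platelets, neurons, and bone were listed for other cell types, and mitochondrial and ribosomal RNA for RNA quality. The annotation lacked 3 of the listed gene names. The miRNA pathway list also held LRBA, a gene for a protein of vesicle trafficking.

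Circles were named by a rule that was fixed with the lists. It took KDM1A circles, up to 10 called circles per direction with separated groups, the 10 smallest p-values where fewer than 5 circles passed, up to 3 members per list, the 5 most abundant circles of each compartment, and circles that changed in kd against Con and back in Re against kd. Others are said to have been chosen after their values were seen.

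The alternatives tried were RLE factors, library totals alone, DESeq2 1.42.0, no filter, the stricter filterByExpr of edgeR with a minimum of 10 counts, the replicate number as a block, only the compared groups, each replicate left out, and an unadjusted p with a fold of at least 2. Settings added after the data were seen were library sizes from circles listed in all 9 libraries, junctions with both ends at exon ends of 1 gene, and totals without the CDYL circle. The pipeline was tested on simulated negative binomial counts. They were drawn from the mean levels, dispersions and effective sizes of all 9 libraries of a compartment, with changes placed on kd. Of 497 simulated cell circles 333 still passed the filter, 128 of them with a 4-fold change, and 14 were recovered (10.9%) with 0 false calls. All recovered shares refer to changed circles that still passed the filter. With a 16-fold change on 136 of 331, 51 were recovered (37.5%) with 2 false calls. In exosomes 1 of 29 circles was recovered at 4-fold (3.45%) and 4 of 29 at 16-fold (13.8%), with 0 and 1 false calls. Tables were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.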

Results

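The libraries listed 2203 circular RNAs in MCF7 cells and 1179 in exosomes, of which 339 were listed in both. In cells, 80.9% had both ends at annotated exon ends of 1 gene, and in exosomes 71.5%. Most were seen once: 1409 of the cell circles and 957 of the exosome circles were listed in 1 library only, and 43 and 10 in all 9 libraries of their compartment. Circles of fibroblast, blood and platelet, neuron and bone marker genes were at 0 in both lists, and 1 exosome circle came from the mitochondrial and ribosomal RNA list.

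The most abundant entry in the cell list was a junction of RPS6KB1, which encodes the ribosomal S6 kinase, with its neighbor VMP1. It lay on chromosome 17 (59838295 to 59910611) and had 269 reads in 9 libraries. The next were SEMA3C exons 6 to 12 with 204 reads, DOCK1 exons 2 to 27 with 192, CAMSAP1 exons 2 to 3 with 177, and a circle inside SEMA4C with 153. In exosomes the most abundant circle was CDYL exon 4, from a gene for a chromodomain co-repressor, with 1034 reads. It was followed by DOCK1 exons 2 to 27 with 534 reads, GSE1 exon 2 with 341, MAN1A2 exons 2 to 5 with 264, and SLTM exons 3 to 5 with 263. CDYL exon 4 held 6.54% ± 1.62 of the junction reads of an exosome library (SD, n = 9), against 11 reads in all 9 cell libraries together.

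KDM1A itself, the gene of LSD1, gave circles with few reads. Exons 2 to 4 (chromosome 1, 23030469 to 23050520) had 2, 0 and 2 reads in Re cells, 0, 6 and 0 in kd exosomes, 16, 5 and 0 in Re exosomes, and 0 in the other groups. Exons 2 to 9 had 3 reads in 1 Con cell library, and exons 4 to 8 had 8 reads in 1 Re exosome library. Con and kd could not be told apart on these circles at this depth.

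Junction reads per library differed between groups. Con cells had 2537 ± 221 listed reads (SD, n = 3; 2393 to 2792), kd cells 1110 ± 148 (1007 to 1280) and Re cells 2579 ± 219 (2413 to 2827). Con exosomes had 1109 ± 33.0 (1071 to 1130), kd exosomes 561 ± 54.6 (500 to 606) and Re exosomes 4091 ± 992 (3339 to 5215). The number of circles listed was 585 ± 30.6, 306 ± 40.7 and 607 ± 35.3 in Con, kd and Re cells, and 155 ± 21, 93.3 ± 15 and 326 ± 45.1 in exosomes. In both compartments each kd library was below each Con and each Re library on reads and circles (exact permutation p = 0.1, two-sided, the smallest 3 against 3 can give; 0.129 adjusted over 18 tests). Re and Con cells overlapped on reads (exact permutation p = 0.6, n = 3), whereas each Re exosome library was above each Con exosome library (exact permutation p = 0.1, n = 3). Mean reads per listed circle were 4.33 ± 0.148, 3.63 ± 0.0445 and 4.24 ± 0.140 in Con, kd and Re cells, and 7.23 ± 0.870, 6.06 ± 0.476 and 12.4 ± 1.26 in exosomes. Values of 2 to 4 reads were on average 75.9% of the listed values of a cell library, 44.2% in Con exosomes, 48.6% in kd exosomes and 20.3% in Re exosomes.

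**Figure D1:**
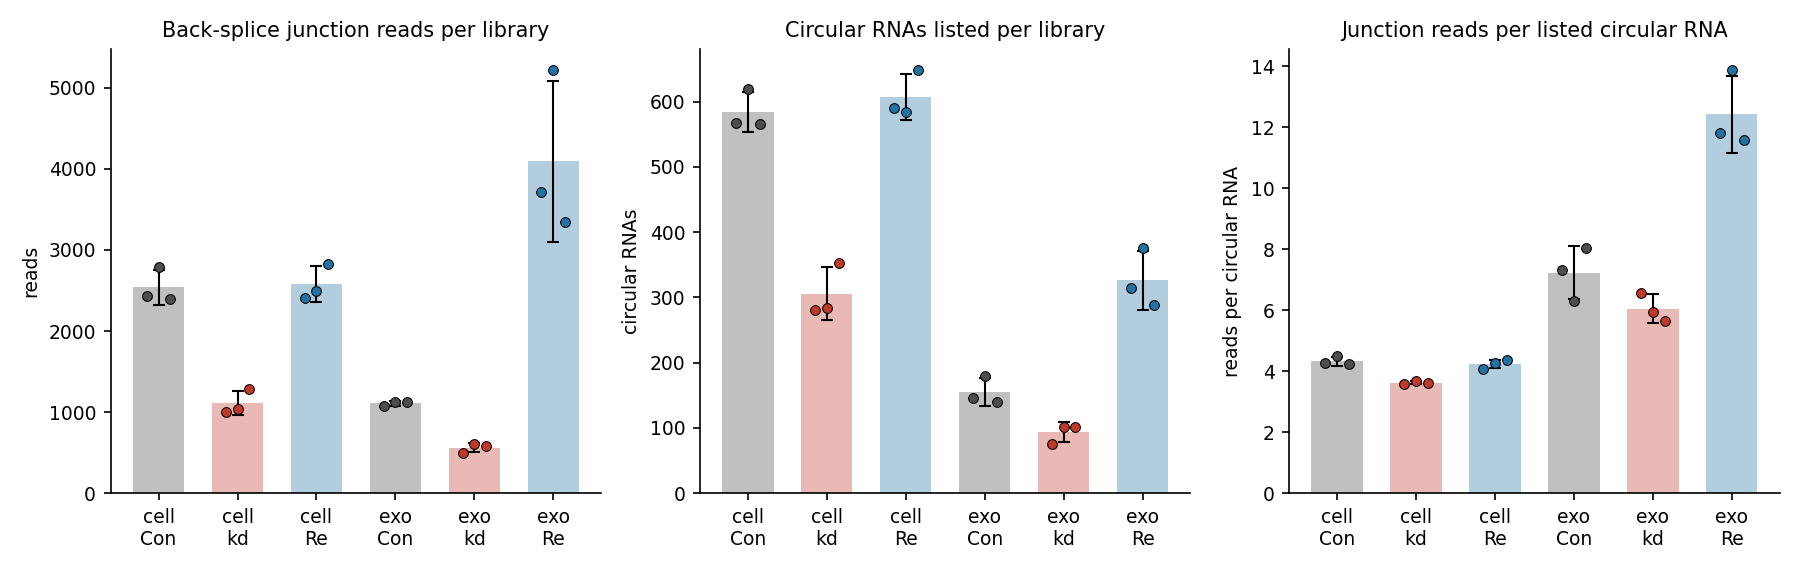
Listed back-splice junction reads (left), circular RNAs listed (center) and junction reads per listed circular RNA (right) in each group; exo stands for exosomes, points are libraries, bars are means and whiskers are SD (n = 3). The kd bars lie at 1110 reads in cells and 561 in exosomes, below 2537 and 1109 in Con, and Re exosomes reach 4091.

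**Figure D2:**
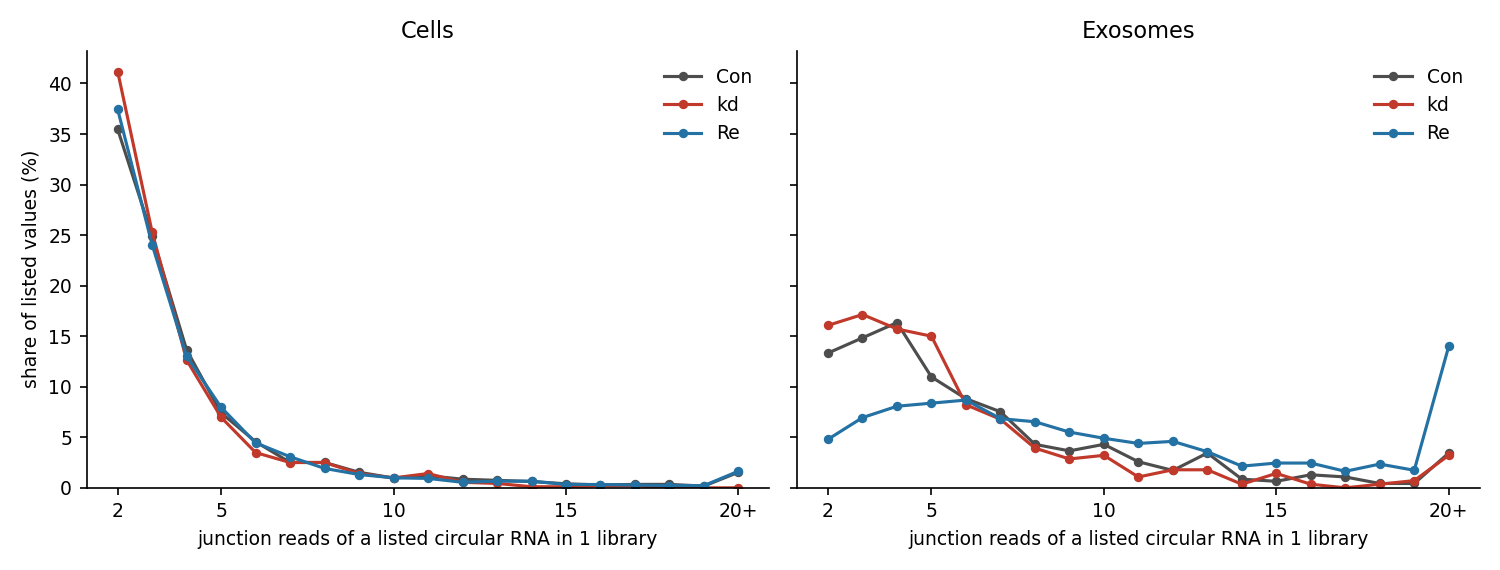
Share of listed values (%, y axis) by the junction reads of a circular RNA in 1 library (x axis, 20 and more pooled) in cells and exosomes; each line is a group of 3 libraries. Cell values were most often 2 reads and Re exosome values most often 6 reads.

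The comparison of kd with Con cells asked which circular RNAs differ with the kd label. A circle of the noncoding gene LINC00632 on chromosome X (140783175 to 140784659) was higher in kd cells, with 11, 7 and 12 reads against 0 in every Con library, at least 15.5-fold (log2 fold change 6.75, SE 1.40, adjusted p = 0.00142, edgeR). The gene CDR1 lies inside this circle on the opposite strand. A circle of CYP24A1 exons 3 to 11, from the enzyme that inactivates vitamin D, rose at least 9.32-fold, with 5, 8 and 5 reads against 0 (log2 fold change 6.08, SE 1.66, adjusted p = 0.0396). DOCK1 exons 2 to 27, from a regulator of Rac in cell migration, fell from 34, 34 and 27 reads to 10, 8 and 5, or from 14.0 ± 2.11 to 5.4 ± 2.11 reads per 1000 effective reads (SD, n = 3). Its log2 fold change was -1.38 (SE 0.36, adjusted p = 0.0266). A junction of IFITM1 with IFITM2, neighboring genes for interferon-induced membrane proteins of similar sequence, had 0, 28 and 11 reads in Con and 0 in kd (log2 fold change -6.53, SE 1.60, adjusted p = 0.0167), so 1 Con library overlapped the kd libraries.

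In all, 2 circles were higher and 2 lower in kd cells among 497 tested, 50 had an unadjusted p under 0.05, and DESeq2 called 2. The groups were separated for 67 circles (13.5%; 10% by chance if no values were tied, and 5.81% over all arrangements of these libraries), 4 higher and 63 lower in kd. Scaled by library totals, DOCK1 had a log2 fold change of -0.83 (adjusted p = 0.453) and IFITM1/IFITM2 an adjusted p of 0.453, while LINC00632 and CYP24A1 stayed called; LINC00632 ended at adjusted p = 0.0572 without kd replicate 3, and CYP24A1 at 0.113 to 0.373 with any of the 6 libraries left out. Without 1 library DOCK1 ranged from adjusted p = 0.0652 to 0.458 except without Con replicate 3, and IFITM1/IFITM2 from 0.239 to 0.464 with each kd replicate left out in turn, while it was no longer tested without Con replicate 2 or 3. With the replicate number as a block CYP24A1 had an adjusted p of 0.108. Over all settings the adjusted p ranged from 0.000116 to 0.0572 for LINC00632, 0.0138 to 0.373 for CYP24A1, 0.000985 to 1 for IFITM1/IFITM2 and 0.00387 to 0.886 for DOCK1.

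The next smallest p-values did not pass. NCAM2 exons 2 to 8, from a neural adhesion molecule, had 8, 18 and 7 reads in Con and 2, 0 and 0 in kd (log2 fold change -3.25, adjusted p = 0.230). The abundant SEMA3C circle, from a secreted semaphorin, had 22, 35 and 27 reads in Con and 11, 9 and 7 in kd (-0.98, adjusted p = 0.305). Log2 fold changes were -1.24 for EMB, -5.94 for ZFAND6 exons 3 to 5, -5.50 for EPB41L5 and -1.47 for the junction of AC104170.1 with OSBPL9. The RPS6KB1/VMP1 junction had a log2 fold change of -0.70 (adjusted p = 0.336).

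By list, 1 of 11 adhesion and epithelial-mesenchymal transition circles was lower (DOCK1; 1 adjusted over the list alone), and PTK2 exons 3 to 10, from focal adhesion kinase, had 3 reads in kd and 0 in Con (adjusted p = 0.336). Of 4 LSD1 and CoREST complex circles 0 passed, over all circles and adjusted over the list alone, with CTBP1 exons 2 to 5 at -1.68 and GSE1 exon 2 at -0.33. None of 13 chromatin modifier circles passed (0 adjusted over the list alone), with BAZ1A exon 3 at -4.71 and KMT2C exons 15 to 23 at -4.11. The same counts of 0 held for 11 estrogen and luminal circles (GRHL2 -5.49), 18 amplified-region circles (PPM1D exons 2 to 3 -5.07), 14 cell cycle circles, 12 ubiquitin ligase circles (RNF13 exons 3 to 8 -4.97, UBR5 exons 2 to 5 -4.72), 5 vesicle biogenesis circles, 4 miRNA pathway circles (LRBA exons 3 to 4 3.70) and 3 biogenesis protein circles (METTL3 exons 2 to 3 0.02). Camera called 0 lists (smallest adjusted p = 0.671; adjusted p = 0.669 with an estimated correlation). Fry, which does not compare a list with other circles, gave directional adjusted p-values of 0.0147 for adhesion (3 positive, 8 negative), 0.0271 for chromatin modifiers (2 and 11) and for ubiquitin ligases (4 and 7), 0.0302 for the amplified regions (5 and 13) and 0.0435 for the estrogen and luminal list (3 and 8). The median of all tested circles was itself at -0.60.

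**Figure D3:**
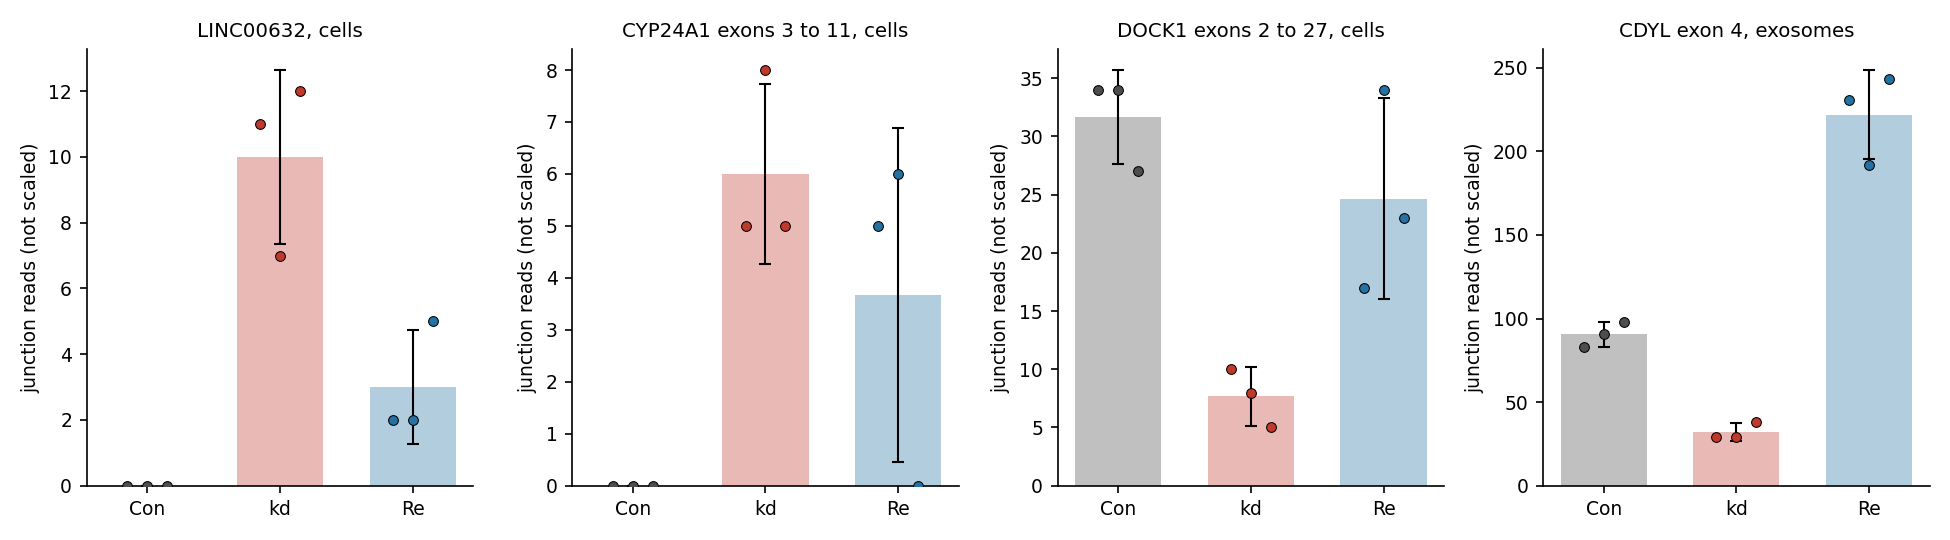
Listed junction reads, not scaled for library size, of the LINC00632, CYP24A1 and DOCK1 circles in cells and of CDYL exon 4 in exosomes, by group; points are libraries, bars are means and whiskers are SD (n = 3). LINC00632 and CYP24A1 were at 0 in all Con cells, DOCK1 had 5 to 10 reads in kd cells against 27 to 34 in Con, and CDYL had 29 to 38 reads in kd exosomes, 83 to 98 in Con and 192 to 243 in Re.

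Re cells were compared with Con cells to see which circles differ between these labels. The LINC00632 circle had 2, 2 and 5 reads in Re cells against 0 in Con (log2 fold change 4.50, adjusted p = 0.609), and CYP24A1 exons 3 to 11 had 5, 6 and 0 (4.81, adjusted p = 0.609). FKBP8 exons 5 to 6, from a mitochondrial co-chaperone, had 4, 8 and 5 reads against 0. The junction of GAPVD1 with RABEPK had 11, 0 and 6 reads in Re and 21, 19 and 16 in Con (-1.65), and GDI2 exons 2 to 6 had 0 in Re and 3, 5 and 7 in Con. None of these passed the test.

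With edgeR 0 circles passed, 35 had an unadjusted p under 0.05 against 24.9 expected by chance, and DESeq2 called 0. The groups were separated for 53 circles (10.7%; 10% by chance without ties, 8.25% over all arrangements). Other circles among the smallest p-values were CORO1C exons 7 to 8 (5.30), the LINC02568/USP3 junction (5.22), PRKD3 exon 2 (5.04), SEMA4C (0.80) and KDM4B exons 6 to 9 (-4.74). All 10 lists with tested circles had 0 members past the threshold and 0 adjusted over the list alone. Examples were SETD3 exons 2 to 6 (1.12) among 13 chromatin modifier circles, ERBB2 exons 7 to 11 (1.05) among 11 estrogen and luminal circles, UBR5 exons 2 to 5 (-4.72) among 12 ubiquitin ligase circles and SNX27 exon 2 (-4.45) among 5 vesicle biogenesis circles. No list passed camera (smallest adjusted p = 0.530; adjusted p = 0.734 with an estimated correlation).

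Re cells were then compared with kd cells. SEMA3C exons 6 to 12 had 35, 30 and 28 reads in Re against 11, 9 and 7 in kd (log2 fold change 1.19, SE 0.34, adjusted p = 0.143). LRBA exons 3 to 4, from a protein of vesicle trafficking, had 0 reads in Re against 4, 8 and 8 in kd (-6.20, adjusted p = 0.143). OSBPL9, which encodes an oxysterol-binding protein, had 23, 27 and 15 reads against 4, 5 and 6 (1.54), EMB had 20, 28 and 18 against 3, 4 and 10 (1.40), and DOCK1 exons 2 to 27 had 17, 34 and 23 against 10, 8 and 5 (1.10, adjusted p = 0.213). None of these passed with edgeR.

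The count was 0 in edgeR, with 47 circles at an unadjusted p under 0.05, and 1 in DESeq2 (LRBA, adjusted p = 0.0299; 0.0299 to 0.512 over the settings). SEMA3C passed when only kd and Re libraries were fitted (adjusted p = 0.0461; 0.0368 to 0.994 over the settings), and IFITM1/IFITM2 without Re replicate 1. The groups were separated for 64 circles (12.9%; 10% by chance without ties, 6.0% over all arrangements), 56 of them higher in Re, and the median log2 fold change was 0.76. The other small p-values were those of AC104170.1/OSBPL9 (1.77), IFITM1/IFITM2 (5.43), CAMSAP1 exons 2 to 3 (1.08), ALMS1 exons 7 to 9 (5.63) and GATAD2B/NUP210L (-5.40). No list had a member past the threshold over all circles. Adjusted over the list alone, 1 of 4 circles of the miRNA pathway list passed (LRBA) and 1 of 11 adhesion circles (DOCK1), with 0 in the other lists. As LRBA encodes a protein of vesicle trafficking, its call does not speak for the miRNA pathway. By camera 0 lists passed (smallest adjusted p = 0.105; adjusted p = 0.386 with an estimated correlation). Of 18 amplified-region circles 15 were positive, with BRIP1 exons 7 to 14 at 5.22 and PPM1D exons 2 to 3 at 4.51, and fry gave a directional adjusted p of 0.00939 for that list, for the adhesion list and for the cell cycle list, 0.0138 for chromatin modifiers and 0.0345 for ubiquitin ligases.

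In exosomes, kd was compared with Con. CDYL exon 4 (chromosome 6, 4891713 to 4892379, 667 bases) fell, with 29, 29 and 38 reads in kd against 83, 91 and 98 in Con. Its level went from 84.8 ± 5.41 to 38.1 ± 9.72 reads per 1000 effective reads (SD, n = 3; log2 fold change -1.16, SE 0.23, adjusted p = 0.000385). As a share of all listed reads it was 7.75% to 8.70% in Con and 4.79% to 6.60% in kd. GSE1 exon 2, from a gene for a partner of the LSD1 complex, had 4, 7 and 5 reads against 13, 34 and 20 (-1.73, adjusted p = 0.302), and CPSF6 exons 2 to 10, from a pre-mRNA cleavage factor, had 0 against 11, 5 and 23 (adjusted p = 0.137); neither passed.

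With edgeR 0 circles were higher and 1 lower among 113, 11 had an unadjusted p under 0.05, and DESeq2 called 0. The CDYL call rested on the scaling: the log2 fold change was -0.51 by library totals (adjusted p = 0.374), -0.53 with RLE factors and -0.53 in DESeq2 (adjusted p = 0.647), and the adjusted p was 0.142 without kd replicate 3, 0.0763 without Con replicate 2 and 0.197 without Con replicate 3 (0.000127 to 0.647 over the settings). The groups were separated for 6 circles (5.31%; 10% by chance without ties, 4.25% over all arrangements). The other small p-values were those of RSRC1 exons 2 to 3 (-6.79), SPECC1 exon 4 (6.08; 7, 4 and 3 reads against 0), KRT19/KRT33B (6.88), BEND7 (-5.99), GRHL2 exon 4 (-3.60), OSBPL9 (-5.86) and RBM33 exons 2 to 5 (-5.23). Of the 2 LSD1 and CoREST complex circles 0 passed over all circles and 1 adjusted over the list alone (GSE1). Among 10 chromatin modifier circles 0 passed either way, with CHD2 exons 32 to 35 at -4.23, and fry gave a directional adjusted p of 0.0110 (2 positive, 7 negative) beside a median of -0.93 over all circles. The 5 estrogen and luminal circles, with KRT19/KRT33B, had 0 either way. Camera called 0 lists (smallest adjusted p = 0.191; adjusted p = 0.262 with an estimated correlation).

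Re exosomes were compared with Con exosomes. SPECC1 exon 4, from a cytoskeletal linker protein, had 41, 8 and 27 reads in Re against 0 in Con (log2 fold change 6.90, adjusted p = 0.447). PUM1 exons 6 to 7, from an RNA-binding translational repressor, had 6, 8 and 12 reads against 0, ASH1L exons 4 to 5, from a histone methyltransferase, had 20, 16 and 12 against 0, and ADAMTS19 exons 4 to 6 had 0 against 3, 10 and 10. CDYL exon 4 stood at 81.6 ± 15.4 reads per 1000 effective reads in Re and 84.8 ± 5.41 in Con (SD, n = 3). As a share of all listed reads it was 3.68% to 7.28% in Re against 7.75% to 8.70% in Con. Each Re library was thus below each Con library, so the likeness of the levels rests on the TMM factors.

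With edgeR 0 of 113 circles passed, 11 had an unadjusted p under 0.05, and DESeq2 called 0. The groups were separated for 16 circles (14.2%; 10% by chance without ties, 8.50% over all arrangements), 12 of them higher in Re. CEP70 exons 7 to 11 (4.73), RBM23 exons 2 to 5 (5.29), SETD3 exons 2 to 6 (5.49), TNRC6A exons 3 to 5 (4.79), ANKRD12 exons 2 to 8 (5.88) and GRHL2 exons 2 to 4 (5.06) completed the 10 smallest p-values, each at 0 reads in Con. Among the lists 0 members passed over all circles, and adjusted over the list alone only TNRC6A, the sole tested member of both the miRNA pathway and the biogenesis protein list, did. Among lists tested by camera 0 passed (smallest adjusted p = 0.748; adjusted p = 0.749 with an estimated correlation).

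In Re against kd exosomes, CDYL exon 4 was higher in Re, with 231, 192 and 243 reads against 29, 29 and 38 (log2 fold change 1.10, SE 0.23, adjusted p = 0.000896). It was the only circle of either compartment called in kd against Con and called with the opposite sign in Re against kd. GSE1 exon 2 had 84, 79 and 95 reads in Re against 4, 7 and 5 in kd, or 31.6 ± 4.97 against 6.32 ± 1.95 reads per 1000 effective reads (SD, n = 3; log2 fold change 2.31, SE 0.68, adjusted p = 0.0699), which did not pass. CPSF6 exons 2 to 10 had 10, 34 and 24 reads against 0 and RSRC1 exons 2 to 3 had 21, 25 and 25 against 0, also without passing.

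With edgeR 1 circle was higher and 0 lower, 16 had an unadjusted p under 0.05, and DESeq2 called 0. By library totals the CDYL change turned to -0.001393 (adjusted p = 0.997), with RLE factors it was 0.32 (adjusted p = 0.544), and the adjusted p was 0.288 without Re replicate 1 and 0.0670 without kd replicate 2, whereas GSE1 passed without Re replicate 2 (adjusted p = 0.0429). Over the settings the adjusted p ranged from 9.22e-05 to 0.997 for CDYL and from 0.0382 to 0.527 for GSE1. The groups were separated for 24 circles (21.2%; 10% by chance without ties, 6.81% over all arrangements), 23 of them higher in Re, and the median log2 fold change was 1.12. The remaining small p-values were those of BEND7 (6.81), CEP70 (4.73), OSBPL9 (6.71), RBM23 (5.29), PUM1 (5.34) and CYP24A1 exons 3 to 11 (-5.67). The LSD1 and CoREST complex list had 0 of 2 circles past the threshold over all circles and 1 adjusted over the list alone (GSE1), and the 10 chromatin modifier circles had 0 either way, with CARM1/SMARCA4 at 6.69 and a directional adjusted p of 0.00424 by fry (7 positive, 3 negative). Camera called 0 lists (smallest adjusted p = 0.533; adjusted p = 0.608 with an estimated correlation).

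The circles that pass kd against Con and turn back in Re against kd numbered 0 in cells and 1 in exosomes (CDYL). If the comparisons were independent, 0.00885 would be expected in exosomes, and simulated unchanged groups that share the kd libraries gave a mean of 0 there and 0.02 in cells over 50 simulations. Changes of opposite sign made up 79.7% of the tested circles in cells, against 68.6% on average and at most 74.8% in the simulations. In exosomes they made up 71.7%, against 65.8% and at most 77.5%. The simulations took the TMM factors as true, so they cannot tell whether the scaling made these patterns. In cells the median log2 fold change for kd against Con was -0.60 with TMM and -0.04 by library totals. For Re against kd it was 0.76 and 0.14. The CDYL pattern was lost with RLE factors, library totals and DESeq2.

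Con exosomes were compared with Con cells to find circles over- or under-represented in the vesicles. CDYL exon 4 was higher in exosomes, with 272 reads against 2 in cells, or 55.3 ± 4.75 against 0.435 ± 0.754 reads per 1000 effective reads (SD, n = 3; log2 fold change 6.74, SE 0.86, adjusted p = 8.85e-07). A junction of FBXW11, a ubiquitin ligase subunit, with STK10 (chromosome 5, 172006458 to 172064812) was at least 12-fold higher, with 40 reads in exosomes and 0 in cells (adjusted p = 0.0159). Among circles lower in exosomes, ZNF124 was lower at least 19.3-fold (52 reads in cells, 0 in exosomes), FAM13B exons 8 to 10 at least 18.6-fold (50 and 0) and SEMA4C at least 16-fold (43 and 0). The abundant cell circles RPS6KB1/VMP1 (114 and 8 reads) and CAMSAP1 exons 2 to 3 (66 and 4) were 15.9-fold and 18.4-fold lower, and RNF13 exons 3 to 9 and FBXW7 exons 3 to 4 fell from 59 to 3 and from 57 to 2 reads.

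With edgeR 2 circles were higher and 18 lower in exosomes among 545, 202 had an unadjusted p under 0.05, and DESeq2 called 36, among them all 20. By library totals 2 circles were called, CDYL and FBXW11/STK10, and folds moved by more than 2 times: at least 7.58 for ZNF124, 7.29 for FAM13B and 6.27 for SEMA4C, 6.23 for RPS6KB1/VMP1 and 7.21 for CAMSAP1, all lower, and at least 30.5 higher for FBXW11/STK10. In every other setting that tested them, these and FAM13B, SPECC1, SEMA4C and ZNF124 were called. The other lower circles were GCN1/MSI1, SPECC1 exon 4, BRIP1 exons 13 to 14, GAPVD1/RABEPK, SETD3 exons 2 to 6, HIPK3 exon 2, XPO1 exons 3 to 5, GUSBP1, ESYT2, SLC38A1 exons 3 to 6 and NCAM2, with log2 fold changes from -7.46 to -4.40. By list, 2 of 12 ubiquitin ligase circles were lower (RNF13 and FBXW7; 8 adjusted over the list alone), 2 of 19 amplified-region circles (RPS6KB1/VMP1 and BRIP1; 3), 1 of 14 cell cycle circles (BRIP1; 1), 1 of 19 chromatin modifier circles (SETD3; 2) and 0 of 5 LSD1 and CoREST complex circles (1, CTBP1 exons 2 to 5 at -6.08). The adhesion, estrogen and luminal, vesicle biogenesis, miRNA pathway and biogenesis protein lists had 0 either way. With camera 0 lists passed (smallest adjusted p = 0.0912 for ubiquitin ligases; adjusted p = 0.169 with an estimated correlation). The median over all circles was -3.78, and by fry 9 lists fell in net direction, the ubiquitin ligase list with adjusted p = 1.49e-07. A circle was tested here if it passed the filter in either compartment, and 497 passed in cells against 113 in exosomes. Most tested circles thus entered through the cell libraries. The filter alone therefore favors lower values in exosomes, and the median and the fry directions cannot be read apart from it. The kits differ between compartments, and these values carry both.

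**Figure D4:**
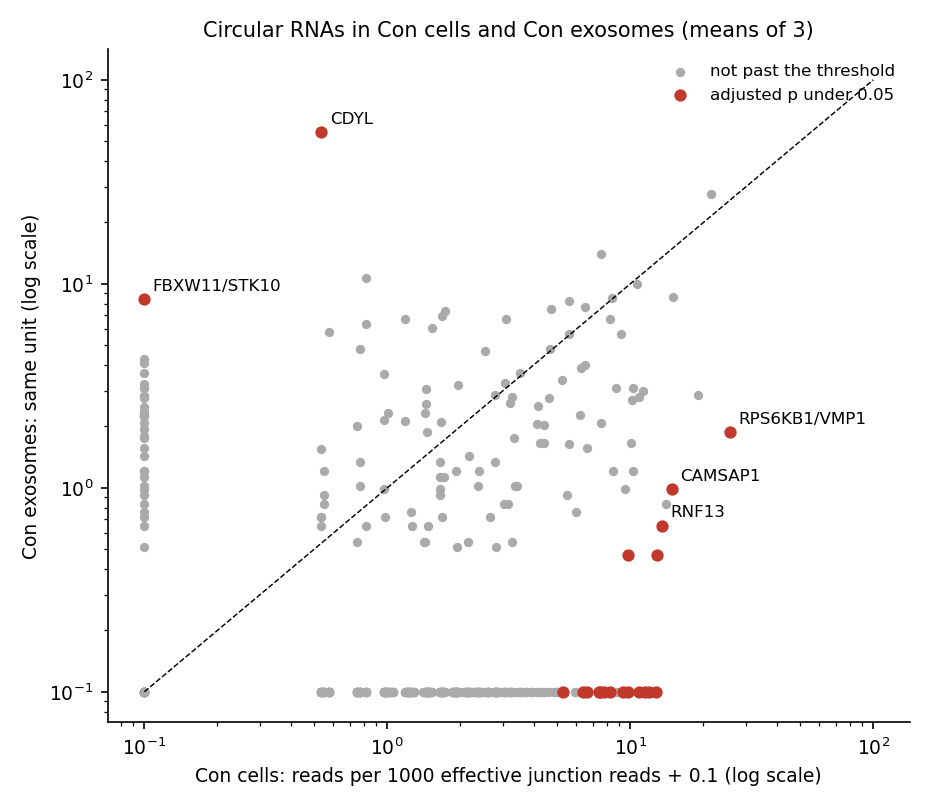
Mean reads per 1000 effective junction reads, plus 0.1, of each tested circular RNA in Con cells (x axis, log scale) and Con exosomes (y axis, log scale), n = 3 libraries each; red points had an adjusted p under 0.05 in edgeR and the dashed line marks equal levels. CDYL and FBXW11/STK10 lie above the line, and the 18 other red points lie below it, most of them at 0 in exosomes.

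Whether kd acted alike in cells and exosomes was asked by the difference between the kd effects. The LINC00632 circle had 0, 0 and 4 reads in kd and 0, 5 and 0 in Con exosomes, against 11, 7 and 12 and 0 in cells (log2 difference -7.72, adjusted p = 0.630). SPECC1 exon 4 had 7, 4 and 3 reads in kd and 0 in Con exosomes, and 9, 3 and 12 in kd and 11, 11 and 14 in Con cells (5.48, adjusted p = 0.630). DOCK1 exons 2 to 27 had 26, 18 and 22 reads in kd and 64, 26 and 46 in Con exosomes, and the difference between compartments was 0.48 (adjusted p = 1).

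With edgeR 0 circles differed, 23 had an unadjusted p under 0.05 against 27.2 expected by chance, and DESeq2 called 0. FARSA exons 6 to 8 (-10.08), GRHL2 (10.58), PHC3 exons 5 to 6 (-9.59), AC068896.1 (-9.58), CPSF6 exons 2 to 10 (-5.13), FUT8 exons 3 to 6 (-9.29), OSBPL9 (-4.37) and TTC6 (8.62) had the other small p-values. All 10 lists had 0 members past the threshold and 0 adjusted over the list alone, and camera called 0 lists (smallest adjusted p = 0.938; adjusted p = 0.900 with an estimated correlation). Over the 65 circles tested in both compartments, the log2 fold changes of kd against Con had a Pearson r of 0.0747 and a Spearman rho of 0.247. Circles are not independent replicates. Of these circles, 46 (70.8%) had the same sign. The medians over all tested circles were -0.60 in cells and -0.93 in exosomes, so shared signs can arise from the TMM centers alone.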

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

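The tests of thinned depth, of the level in kd, of paralogs, of random joining, of few molecules, of the content of Re exosomes and of chromatin hosts were chosen only after the results were seen.

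Compartments were compared in how group changed reads per listed circle, and none of these differences passed after adjustment. From Con to Re the ratio of reads per circle was 0.979 in cells and 1.72 in exosomes, a log2 difference of 0.81 (exact permutation p = 0.03, two-sided, n = 3 per group; 0.12 adjusted over 12 tests), which stood out only before adjustment. When libraries were thinned to equal reads, 1007 in cells and 500 in exosomes, kd listed 1.12 times as many circles as Con in cells and 0.833 times as many in exosomes. That is a log2 difference of -0.43 (exact permutation p = 0.005, the smallest possible, n = 3; 0.03 adjusted). From kd to Re the ratios were 0.890 and 1.28, a log2 difference of 0.53 (exact permutation p = 0.005, n = 3; 0.03 adjusted). The minimum of 2 reads biases such thinning. When Con cells were instead thinned to the kd mean of listed reads, they listed 326 circles against 306 in kd, so the direction in cells turned with the way of thinning, while exosomes kept theirs (118 against 93.3).

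Fewer junction reads and fewer circles were listed in kd than in Con, which may stem from lower sequencing depth, from a lower level of circular RNA, or from the loss of a few abundant circles. Con cell libraries thinned to the kd mean, keeping 51.3% of reads, listed 326 circles against 306 ± 40.7 in kd (SD, n = 3), and thinned Con exosomes listed 118 ± 10.8 against 93.3 ± 15. The 10 most abundant circles of Con cells held 10.5% of the reads lost, which argues against a few abundant circles such as RPS6KB1/VMP1. The ratio of kd to Con reads was 0.438 in cells and 0.506 in exosomes, and a uniform loss of that size gives the same picture whether depth or level fell. Depth and level stay open, as mapped reads per library are not in the files.

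Junctions that joined exon ends of neighboring genes recurred across libraries. RPS6KB1/VMP1 had 269 cell reads, GTF2I/GTF2IRD1 137 cell and 189 exosome reads, FBXW11/STK10 5 and 202, and GCN1/MSI1 102 and 0. Reads shared between paralogs, random joining of molecules, and a rearranged or amplified genome are candidate explanations. Pairs were taken as paralogs when their gene names were the same up to the first digit, short beginnings excepted. Sequences were not compared, so paralogs with unlike names would be missed. Pairs taken as paralogs made up 17.1% of the reads on such junctions in cells and 21.5% in exosomes. This argues against reads shared between like-named paralogs as the main source. Of 56 such cell junctions without paralogs, 25 (44.6%) were also listed in exosomes, made with another kit, against 274 of 1782 circles (15.4%) at exon ends of 1 gene. Among circles listed in as many cell libraries the odds ratio was 2.28 (exact Mantel-Haenszel p = 0.0133 across circles). This was the third test tried of random joining, and its p was not adjusted for the earlier tries. It argues against joining that is random alone. Circles were not matched by read level, so joining that depends on abundance stays open. Of circles in all 9 cell libraries, 5 of 6 and 24 of 29 were also in exosomes. Hosts in the amplified list were 3.57% of the neighbors without paralogs and 2.39% of other circles (Fisher p = 0.397). The list names genes of amplified regions and holds no breakpoints, so a rearranged genome stays open.

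Re exosome libraries held many reads per circle. Only 20.3% of their listed values were 2 to 4 reads, against an average of 75.9% in the cell libraries, 44.2% in Con and 48.6% in kd exosomes. This restates the many reads per circle and does not decide whether many copies of few starting molecules were sequenced. Poor overlap was common to all exosome groups: of circles with at least 10 reads in 1 library, 86.6% in Re, 70.4% in Con and 60% in kd exosomes were at 0 in another, against 9.09% in Con cells, and 6.01%, 5.76% and 7.02% of listed circles were in all 3 libraries. The top 10 circles held 20.8% of the reads, which argues against a few circles such as CDYL taking most counts. Few molecules stay open, and so does content of exosomes that differs in Re, with a smallest adjusted p of 0.447 in Re against Con (edgeR).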

How the results depend on the processing

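The count for kd against Con in cells was 4 and moved to 1 with RLE factors, 2 with library totals, 2 with DESeq2, 2 with no filter, 1 with filterByExpr, 1 with sizes from circles in all libraries, 2 with one-gene exon ends and 48 at an unadjusted p with a fold of at least 2. Leaving out 1 library gave 0 to 2. The split was 2 higher and 2 lower, and 2 higher and 0 lower with library totals and with DESeq2. LINC00632 held in all but 1 setting (adjusted p = 0.000116 to 0.0572, edgeR, or DESeq2 in that setting). CYP24A1 ranged over 0.0138 to 0.373, IFITM1/IFITM2 over 0.000985 to 1 and DOCK1 over 0.00387 to 0.886.

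For Re against Con in cells the count was 0, with 33 at an unadjusted p and fold of at least 2 and 0 to 0 with 1 library left out. For Re against kd in cells it was 0, and 1 with DESeq2 (LRBA), 1 with the replicate block and 1 with only the compared groups (SEMA3C in both), 46 at an unadjusted p and fold of at least 2, and 0 to 1 with 1 library left out.

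For kd against Con in exosomes the count of 1 (CDYL) went to 0 with RLE factors, library totals, DESeq2, no filter, filterByExpr, sizes from circles in all libraries, one-gene exon ends and CDYL out of the totals. It was 11 at an unadjusted p and fold of at least 2 and 0 to 1 with 1 library left out. CDYL had adjusted p = 0.000127 to 0.647. For Re against Con in exosomes the count was 0, with 11 at an unadjusted p and fold of at least 2, and 0 to 0 with 1 library left out. For Re against kd in exosomes the count of 1 (CDYL) went to 0 with RLE factors, library totals, DESeq2, no filter, only the compared groups, sizes from circles in all libraries and one-gene exon ends, to 2 with filterByExpr (CDYL and GSE1) and to 16 at an unadjusted p and fold of at least 2, and was 0 to 2 with 1 library left out. CDYL turned to a log2 fold change of -0.0013931 with library totals, and its adjusted p ranged over 9.22e-05 to 0.997.

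For exosomes against cells the count was 20, and 2 with library totals, 36 with DESeq2, 7 with no filter, 202 at an unadjusted p and fold of at least 2, and 8 to 17 with 1 library left out. The split was 2 higher and 18 lower, and 2 higher and 0 lower with library totals. CDYL stayed called in all settings, with adjusted p = 2.43e-18 to 3.66e-06 (edgeR, or DESeq2 in that setting). For the difference between the kd effects the count was 0, with 23 at an unadjusted p and fold of at least 2 and 0 to 0 with 1 library left out.

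Circles that changed in kd and back in Re numbered 0 in cells, 0 to 0 with 1 kd library left out. In exosomes the count of 1 went to 0 with RLE factors, library totals, DESeq2, no filter, filterByExpr, only the compared groups, sizes from circles in all libraries, one-gene exon ends and CDYL out of the totals, and was 0 to 1 with 1 kd library left out. The correlation of kd effects was 0.0747, and -0.0815 with no filter, and -0.0100 to 0.224 with 1 library left out.

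Circles listed per library with a minimum of 5 reads numbered 152, 64 and 155 in Con, kd and Re cells and 86, 47.7 and 262 in exosomes. Thinned to equal reads they numbered 250.42 in Con and 249.707 in Re cells, and 107 in Con and 114 in Re exosomes, against 281 and 89.3 in kd. With 1 library left out the means were 567 to 594, 282.5 to 318.5 and 587 to 619 in cells, and 143 to 162.5, 89 to 102 and 301.5 to 345.5 in exosomes. Gene lists passed by camera stayed at 0 in all settings.

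Within a compartment, same-numbered libraries of different groups were no more alike than other pairs. Their correlations were -0.0412 to 0.0624 in cells and -0.142 to 0.145 in exosomes, within -0.0585 to 0.0954 and -0.264 to 0.235 for other pairs. At counts this low, counting noise can hide a shared batch, so pairing is not excluded. Correlations between cell and exosome libraries of the same number were not computed. With the replicate number as a block the count was 3 for kd against Con in cells, with CYP24A1 lost, and 19 for exosomes against cells. The pseudocount and low-value filter planned for normalized values were not run, since the files hold counts, for which the count filters above were run instead. The cause of each difference between settings was not tested. Whether depth or the spread between libraries limited the calls was not tested. In simulated data, 10 of 21 changed circles among the 50 most abundant in cells were recovered at 4-fold and 1 of 12 in exosomes, where the common biological coefficients of variation were 0.893 and 1.46.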

Other observations

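The chromatin host test was chosen only after the result was seen, while the length test and the splits were fixed before.

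Genes for chromatin modifiers hosted a larger share of circles in exosomes than in cells. Each exosome library had 6.74% ± 1.38 of its listed circles in such hosts and each cell library 3.41% ± 0.458 (SD, n = 9; exact permutation p = 4.11e-05, two-sided, the smallest possible). CHD2, a chromatin remodeler, gave 8 circles with 65 reads in exosomes and 4 with 14 in cells. NCOR2, a nuclear co-repressor, gave 8 with 146 and 3 with 12. PHC3, of the Polycomb complex, gave 6 with 149 and 6 with 16, and ATRX and CHD6 gave 3 each in exosomes (40 and 87 reads) and 0 in cells. Other hosts went the other way, with 122 reads in cells against 19 in exosomes for KDM2A, 89 against 29 for SETD3, 58 against 15 for KMT2C (5 circles against 2) and 58 against 3 for ASXL1. Of circles listed in 1 compartment only, 50 of 840 in exosomes and 44 of 1864 in cells had such hosts (Fisher p = 6.67e-06 across circles, which are not independent). Adjusted over the 15 lists, this Fisher p was 0.0001, and the next smallest was 0.435. The permutation test above treated the 9 libraries of a compartment as exchangeable, although they carry 3 labels. The genes above were chosen after their values were seen. The kits differ between compartments, so the share may reflect the library kit as well as the vesicles.

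Circles were no shorter in exosomes. The median exonic length per library was 525 ± 46.5 bases in exosomes and 502 ± 14.2 in cells (SD, n = 9; exact permutation p = 0.161, two-sided).

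Regrouping the libraries gave counts to set beside the real ones, and 10 splits of 6 libraries are too few for a share under 0.05. For kd against Con the real count was 4 in cells and 1 in exosomes, and the highest other was 1 and 0, so 1 of 10 splits reached the real count in each. For Re against kd in exosomes the real count was 1 and the highest other 0 (1 of 10), and for exosomes against cells 20 and 0 (1 of 10). For Re against Con and for Re against kd in cells, and for Re against Con in exosomes, the real count was 0, the highest other was 1, 0 and 0, and 10 of 10 splits reached it. For the difference between the kd effects the real count was 0, and 100 of 100 regroupings reached it.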
